A study of Mus musculus with 9 samples.

How the data were processed

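The deposited table held gene-level expected counts, which per the submitters' processing notes were made with RSEM 1.2.3 after base calling with CASAVA 1.8.2 and adapter trimming with cutadapt 1.3, against GRCm38 and Ensembl release 76. The aligner used inside RSEM and the strandedness of the libraries are not given in the sources used here. Per the labels, cells came from ventricles at embryonic day 17.5 after tamoxifen at day 15.5. They were sorted at the same time as viable Ter119-negative, CD45-negative, CD31-positive cells, with endomucin and Tomato setting the coronary populations apart. The endocardial gate as written names CD31 and GFP but neither of these, so that it may hold other endothelial cells. RNA was sequenced as single reads. All 9 columns were mapped to the 9 samples by their group and replicate number.

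Of 41214 features, 40254 (97.67%) had a gene symbol and 12066 had no count in any library. Of the values above 0, 45.5% were not whole numbers, and all values were rounded to whole counts before testing. Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust), with TMM scaling and the filter for low counts of edgeR (minimum count of 10), which left 17103 genes. A single fit held all 9 libraries with 1 mean per population, and its common dispersion was 0.409 (coefficient of variation 0.639). Comparisons were arterial minus venous, endocardial minus the mean of arterial and venous on the log scale, arterial minus endocardial and venous minus endocardial. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes, and counts adjusted over a list alone used the same threshold. CPM values used the TMM library sizes. Coordinates came from GENCODE release 21 for mouse.

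The characteristic that numbers the batches equals the replicate number, so that libraries of the same number may share a sort. Correlations of the deviations from the population means between libraries of the same number were 0.083 to 0.165 for number 1, 0.036 to 0.146 for number 2 and -0.09 to 0.092 for number 3, and the library most correlated with each library had the same number in 5 of 9 cases. These correlations do not exclude a shared pool, as replicate 2 had the highest Xist and the lowest Ddx3y in each population (see the other observations). The fit without a block is reported. It called 183 genes for arterial against venous and 2379 for endocardial against coronary libraries, against 225 and 2722 with the block. A value with the replicate block is given where it changes a call. Each batch holds 1 library per population and allows no test of its own, so that the direction within batches is given as counts. The first 2 principal components took 26.9% and 21.5% of the variance. Endocardial replicate 1 stood apart from its group, at 35.0 and 139 on these components against 115 and 1.80 for replicate 2 and 117 and -16.2 for replicate 3. It had 21101 genes with a count above 0, against 17337 and 17130. Correlations between libraries of a population were 0.869 to 0.901 for arterial, 0.843 to 0.89 for endocardial and 0.925 to 0.947 for venous libraries, and no 2 libraries were identical.

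A set of 31 gene lists was written by hand. The endothelial lists covered arterial, venous, capillary, endocardial, lymphatic and pan-endothelial markers, and the list of tip cell and VEGF response. The pathway lists covered Notch, BMP and TGF-beta, Wnt, ephrins with semaphorins and axon guidance, fluid shear stress, hypoxia and glycolysis, fatty acid uptake and oxidation, oxidative phosphorylation, DNA replication, mitosis, cell cycle inhibitors, basement membrane and elastic matrix, chemokines with antigen presentation and inflammation, and the endothelial to mesenchymal transition with valve genes. Lists of other cell types covered cardiomyocyte, fibroblast, mural, epicardial, leukocyte, erythroid with platelet, and neural markers, and technical lists covered immediate-early genes, mitochondrially encoded genes and sex-linked genes. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 31 lists of a comparison, and again with an estimated correlation and with fry. The value with an estimated correlation is printed where it ended the call. Members at 0 in 1 population were also set to a floor of 3 counts per library to bound the list medians.

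Named genes followed a rule written before the files were seen. It took the 10 largest rises and falls of the arterial to venous and the endocardial to coronary comparison and 5 of each for the other comparisons, among called genes with a mean log2 CPM of at least 4 and no overlap between the libraries compared. Predicted genes, pseudogenes, Y-linked genes and Xist were left out of it. The rule added up to 4 list members with the smallest p and up to 2 against the direction of a list, and 24 key genes named in each comparison. Not every gene of the rule is named in the text, and a result withheld for evaluation is not reported here. Exceptions chosen after their values were seen are Fos, Ogn, Lyve1, Pdpn, Itga9, Sox18, the sex-linked and the imprinted genes named among the other observations.

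In a self-test, counts were simulated for each gene independently, from its mean over all libraries and its fitted dispersion. In these, 100 genes were changed 2-fold and 100 changed 4-fold, and none was taken from the genes of lowest expression. For arterial against venous, 9% and 62% were recovered, and 4 of 75 genes called were unchanged. For endocardial against coronary, 29% and 67% were recovered, and 16 of 113 genes called were unchanged. The changed list was called in each case, and among 30 random lists camera made no call. Simulated genes were uncorrelated, so that this does not test the preset correlation for the real lists.

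Alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors in edgeR, no filter, a filter at 5 CPM in 3 libraries, the replicate block, only the libraries of the groups compared, a minimum of 2-fold, and each library left out in turn. Leaving out whole batches, and leaving out Gm42418 with the mitochondrially encoded genes, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.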

Results

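The series profiled gene expression in endothelial cells sorted from the ventricles of mouse embryos at E17.5, when the coronary vessels of the heart wall and the endocardium, the inner lining of the chambers, lie side by side. The 9 libraries used here were 3 replicates of each of 3 sorted populations. The arterial population was enriched for intramyocardial arteries and capillaries, the venous population for subepicardial veins, and the endocardial population for endocardium. The arterial and venous populations together are called coronary below. Each library held between 12750553 and 19474419 counts. Genes with a count above 0 numbered 19610 to 21221 in the arterial, 17130 to 21101 in the endocardial and 18462 to 19755 in the venous libraries. The predicted gene Gm42418 took 3.30% to 11.1% of the counts of a library. Levels are given in CPM, the usual depth-normalised count unit, after TMM scaling, with the SD over 3 libraries. Fold changes are on the log2 scale with a standard error (SE). The SE was derived as the absolute log2 fold change divided by the square root of the F statistic. The labels do not state that replicates came from separate animals or pools. The p-values of genes thus measure the spread between these libraries, which may be technical. Not all of it need be technical, as the same replicate number had the highest Xist and the lowest Ddx3y in each population. A camera p-value of a list compares its members with all other genes at a low preset correlation, and does not measure that spread alone.

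Genes of the sort itself were checked before any comparison. Emcn, the endomucin used to set the coronary gates, stood at 679 ± 65.6 CPM in the endocardial libraries, 199 ± 38.3 in the arterial and 249 ± 18.5 in the venous ones. Nes, whose promoter drove the reporters of the sort, stood at 521 ± 16.8 CPM in arterial, 448 ± 116 in venous and 149 ± 1.07 in endocardial libraries. Pecam1, which encodes the CD31 antigen common to all gates, had 1130 ± 161, 934 ± 92.9 and 753 ± 101 CPM in the same order. Because cells were selected on these products, their levels describe the sorts and are not read as results of the comparisons. The endocardial gate as written names CD31 and GFP but no endomucin or Tomato condition, so that other endothelial cells in that sort are not ruled out.

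The arterial-enriched and venous-enriched populations were compared to ask which genes separate the 2 kinds of coronary endothelium. Arterial libraries had higher levels of the arterial gap junction genes Gja5 (connexin 40) and Gja4 (connexin 37), the chemokine receptor gene Cxcr4 and the Notch pathway genes Jag1 and Hey1. Venous libraries had higher levels of the venous transcription factor gene Nr2f2 and the apelin receptor gene Aplnr, and also of fibrillar collagen and endocardial genes. Gja5 (chromosome 3, 96904693 to 97077416, plus strand, GRCm38) rose from 4.40 ± 1.58 CPM in venous to 81.4 ± 20.7 CPM in arterial libraries. The rise was 18.5-fold (log2 4.21 ± 0.34, adjusted p = 2.86e-06, edgeR). Among called genes with a mean log2 CPM of at least 4 and no overlap between the groups, the largest fall was that of Col1a1 (chromosome 11, 94936224 to 94953042, plus strand), a chain of type I collagen, from 149 ± 27.5 CPM in venous to 6.04 ± 2.50 CPM in arterial libraries (log2 -4.63 ± 0.33, adjusted p = 1.67e-06). Of 17103 genes tested, 53 were higher and 130 lower in arterial than in venous libraries at an adjusted p under 0.05. All 183 went in the same direction in each of the 3 batches, against 34% of all genes tested, and called genes are selected for such agreement.

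Of the 24 tested arterial markers, 13 were higher in arterial libraries and 11 were not called (16 higher adjusted over the list alone), with a median log2 fold change of 1.33 and adjusted p = 1.34e-30 for the list (camera). Gja4 (chromosome 4, 127311421 to 127314039, minus strand) had 55.4 ± 17.4 CPM against 7.69 ± 1.60 and Jag1 105 ± 25.0 against 35.7 ± 5.50, with adjusted p of 8.3e-05 and 0.00146. Cxcr4 was 4.28-fold higher and Hey1 rose by 1.60 ± 0.23 on the log2 scale. Mecom, a zinc finger transcription factor gene, rose by 1.33 ± 0.17 on the log2 scale (adjusted p = 0.000376). Other genes with large folds were Enpp2, encoding the lysophospholipase D autotaxin (4.96-fold), the kinase gene Tec (4.46-fold), the lipoxygenase gene Alox12 (4.29-fold), the sialyltransferase gene St8sia6 (4.11-fold) and Slc45a4 (4.72-fold). The proprotein convertase gene Pcsk5 rose by 1.93 on the log2 scale. Levels of the chemokine gene Cxcl12 were 245 ± 100 CPM in arterial and 22.8 ± 10.4 CPM in venous libraries (adjusted p = 0.00941). Its call ended without endocardial replicate 1 (0.0572), venous replicate 2 (0.0713) or venous replicate 3 (0.0575). The ephrin gene Efnb2 was 1.85-fold higher (adjusted p = 0.00698). That call ended without venous replicate 2 (0.0588). Dll4, a Notch ligand gene, missed the threshold at 120 ± 38.3 against 63.8 ± 19.7 CPM (adjusted p = 0.282) and passed it without arterial replicate 1 (0.0365). Sox17 had 59.1 ± 6.25 and 39.5 ± 5.43 CPM (adjusted p = 0.769).

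Of the 15 venous markers, 5 were lower in arterial libraries and 10 were not called (6 lower adjusted over the list alone), with a median of -0.82 and adjusted p = 2.62e-14 for the list. Nr2f2 (chromosome 7, 70351944 to 70366735, minus strand) was 2.81-fold lower, and Aplnr (chromosome 2, 85136225 to 85139923, plus strand) had 384 ± 54.4 CPM in venous and 155 ± 38.9 CPM in arterial libraries, with adjusted p of 0.000547 and 0.00182. The carboxypeptidase gene Cpe fell by 2.36 ± 0.27 on the log2 scale. The venous markers Ephb4 (51.1 ± 13.7 CPM in arterial, 80.7 ± 40.2 in venous libraries) and Vwf (89.5 ± 24.7 and 53.1 ± 20.6) were not called, at adjusted p of 0.858 and 0.839.

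Markers of the endocardium were also lower in arterial than in venous libraries. Of 20 tested, 10 were lower and 10 were not called (15 lower adjusted over the list alone), with a median of -2.52 and adjusted p = 2.19e-47 for the list. Log2 fold changes were -3.26 ± 0.22 for the T-box factor gene Tbx20, -2.04 ± 0.18 for the adhesion receptor gene Adgrg6, -2.76 ± 0.25 for the cadherin gene Cdh11 and -2.43 ± 0.27 for Tmem108. Their adjusted p lay between 4.9e-07 and 9.32e-05. In the venous libraries these genes stood at 136, 13.4, 49.7 and 14.2 CPM, against 88.0, 431, 997 and 242 CPM in the endocardial libraries. Among 10 lymphatic markers 3 were lower and 7 were not called (1 higher and 3 lower adjusted over the list alone; adjusted p = 3.26e-07). Their median was -1.43, or -1.29 with Ccl21a at the bound set by a floor of 3 counts per library. The lymphatic transcription factor gene Prox1 had 7.30 CPM in arterial and 18.3 in venous libraries (adjusted p = 0.0112), and its call ended without venous replicate 1 (0.0587). Npr3 (25.7 and 49.0 CPM), Nfatc1 (50.1 ± 7.25 and 57.9 ± 1.29) and Plvap (1.05 ± 0.66 and 8.63 ± 4.16) were not called, at adjusted p of 0.278, 0.882 and 0.106, and Plvap passed without endocardial replicate 1 (0.0297).

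Fibroblast markers moved with the venous and endocardial markers. In arterial libraries 9 of 15 were lower and 6 were not called (15 lower adjusted over the list alone; adjusted p = 2.89e-100). The median was -4.05, or -3.90 with Dpep1, which had no count in the arterial libraries, at the same kind of bound. Col3a1 (chromosome 1, 45311538 to 45349706, plus strand), a chain of type III collagen, had 23.3 ± 9.53 CPM in arterial, 526 ± 68.1 in venous and 289 ± 18.9 in endocardial libraries. The type I collagen gene Col1a2 had 9.35 ± 3.26, 155 ± 18.6 and 126 ± 30.8 CPM in the same order. Periostin (Postn) had a log2 fold change of -3.25 ± 0.16 and the growth factor receptor gene Pdgfra one of -3.44 ± 0.24. The plot of the fibroblast list shows each member per library.

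**Figure D1:**
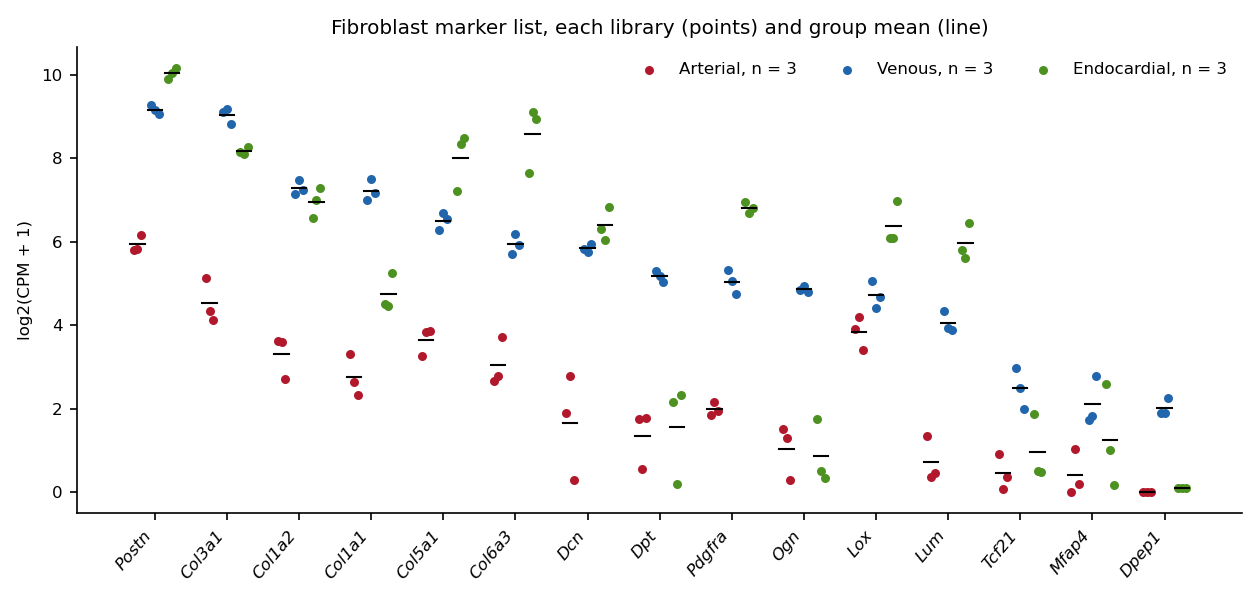
Expression of the 15 tested fibroblast markers as log2(CPM + 1), with 1 point per library, a line at the mean of 3 libraries and colours for the populations. The venous means lie above the arterial means for every gene plotted, with Col3a1 at 526 CPM in venous and 23.3 CPM in arterial libraries on the linear scale.

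Lists of valve, BMP and TGF-beta, Wnt and matrix genes were also lower in arterial libraries, the last 3 on the preset correlation only. In the list of endothelial to mesenchymal transition and valve genes, 4 of 23 were lower and 19 were not called (1 higher and 6 lower adjusted over the list alone; adjusted p = 9.38e-10), including the proteoglycan gene Vcan, which fell by 3.35 ± 0.31. That list shares Cdh11, Nfatc1, Foxc1 and Bmp2 with the endocardial list and Postn with the fibroblast list, so that it is not separate evidence. The BMP and TGF-beta list of 30 had 3 lower genes, Tgfbi, Bmp6 and Bmpr1a, and 27 not called (5 lower adjusted over the list alone). Its adjusted p was 3.2e-06, and adjusted p = 0.0518 with an estimated correlation. Tgfbi, encoding a secreted matrix protein, had 28.1 ± 4.23 CPM in venous and 1.98 ± 0.44 CPM in arterial libraries. The Wnt list (3 lower, 26 not called, 6 lower adjusted over the list alone) had adjusted p = 0.00789 and lost its call with adjusted p = 0.0886 with an estimated correlation and without arterial replicate 1 (0.051). The summed counts of the Wnt members went the other way. They took 0.2525%, 0.243% and 0.2201% of counts in arterial replicates 1, 2 and 3, against 0.2281%, 0.1974% and 0.1963% in the venous ones. The list of basement membrane and elastic matrix (1 higher, 3 lower, 28 not called; 1 and 7 adjusted over the list alone) had adjusted p = 0.000311, adjusted p = 0.399 with an estimated correlation and 0.051 without arterial replicate 1. Its fibrillin gene Fbn2 fell by 2.55 ± 0.25 (adjusted p = 2.53e-05).

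Further lists were called, most of them on the preset correlation only. The DNA replication list was lower in arterial libraries with a median of -0.43 (adjusted p = 5.32e-07), and the mitosis list with a median of -0.36 (adjusted p = 7.45e-06, and adjusted p = 0.189 with an estimated correlation). No single gene of these 2 lists of 32 was called by edgeR or DESeq2, while 9 and 7 had an unadjusted p under 0.05 in edgeR. Mki67, a proliferation marker, had 1440 ± 403 CPM in arterial and 1940 ± 369 in venous libraries (adjusted p = 0.554). The oxidative phosphorylation list was lower with a median of -0.19 (adjusted p = 0.00318, and adjusted p = 0.328 with an estimated correlation), and the mitochondrially encoded genes with a median of -0.47 (adjusted p = 1.41e-05, and adjusted p = 0.0931 with an estimated correlation). Cardiomyocyte markers (1 lower, 20 not called, 4 lower adjusted over the list alone) had a median of -0.55 (adjusted p = 1.05e-05, and adjusted p = 0.136 with an estimated correlation). Mural cell markers (1 higher, 14 not called, 3 higher adjusted over the list alone) had a median of 0.65 (adjusted p = 0.0182, and adjusted p = 0.136 with an estimated correlation). That call ended without arterial replicates 2 or 3 or venous replicates 1 or 3, at 0.0638 to 0.191. The neural list (1 higher, 7 not called, 1 higher adjusted over the list alone) had a median of 1.22 and adjusted p = 0.00293, and adjusted p = 0.136 with an estimated correlation, and stood at 0.05 without arterial replicate 1. Immediate-early genes had a median of 0.18 (adjusted p = 0.0104, and adjusted p = 0.214 with an estimated correlation), and the call ended without arterial replicates 1 or 2 or venous replicates 2 or 3, at 0.052 to 0.207.

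The other 14 lists were not called between arterial and venous libraries, at adjusted p from 0.101 to 0.954. They were the capillary, pan-endothelial, tip cell, Notch, ephrin and guidance, shear stress, hypoxia, fatty acid, cell cycle inhibitor, chemokine, epicardial, leukocyte, erythroid and sex-linked lists. A few passed with 1 library left out, the capillary list without arterial replicate 1 (0.0252), the fatty acid list without arterial replicate 2 (0.0253) or venous replicate 1 (0.0252), and the hypoxia list without venous replicate 1 (0.0384). With fry in limma, calls were lost for mitosis (adjusted p = 0.0623), oxidative phosphorylation (0.136), matrix (0.247), immediate-early (0.0874) and mural genes (0.058), and gained for cell cycle inhibitors (0.0212) and chemokines (0.0355). The capillary gene Fabp4 had 1280 ± 143 and 1360 ± 71.9 CPM (adjusted p = 0.961) and Kdr, the VEGF receptor 2 gene, 1950 ± 497 and 1650 ± 288 CPM (adjusted p = 0.866). Neither Car4 (17.9 ± 8.46 and 22.7 ± 12.9 CPM, adjusted p = 0.934) nor Apln (128 and 202 CPM, adjusted p = 0.334) was called.

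Several genes with large arterial to venous folds were near 0 in the arterial libraries, so that a single library moved their fold. Lum (0.73 ± 0.71 CPM in arterial, 15.8 ± 3.10 in venous libraries) had a log2 fold change of -4.45, and -5.58 without arterial replicate 1. Inhba (0.79 ± 0.63 and 9.10 ± 1.05 CPM) moved from -3.48 to -4.07 without arterial replicate 2. The cytokine-like gene Cytl1 (0.0768 and 1.78 CPM) had counts in arterial replicate 2 only, so that its log2 fold change of -4.22, and -7.78 without that library, are fitted values and not measured folds. Myof (1.17 ± 1.28 and 21.8 ± 7.28 CPM, adjusted p = 0.0335) kept its call only without arterial replicates 1 or 3, at 0.0723 to 0.228 without any of the other 7 libraries. Its log2 fold change moved from -4.22 to -5.45 without arterial replicate 1. The claudin gene Cldn11 (0.203 ± 0.235 and 3.93 ± 2.17 CPM, adjusted p = 0.0217) lost its call with the replicate block (0.0848) and without arterial replicate 1 (0.152) or venous replicates 1 (0.114) or 3 (0.108). Its log2 fold change moved from -4.12 to -5.63 without arterial replicate 2. Hapln1, encoding a hyaluronan link protein, was not near 0 (5.15 ± 2.36 and 62.4 ± 38.1 CPM, log2 -3.60, adjusted p = 0.0125). It lost its call without arterial replicates 2 (0.0973) or 3 (0.0558), endocardial replicate 1 (0.0592) or venous replicate 3 (0.0844), with log2 fold changes from -3.61 to -3.38. The count of 183 genes was 120 without venous replicate 1, 405 with DESeq2 and 439 without a filter on low counts. With 2 libraries per group, a setting chosen after seeing the data, it was 66 without replicate 2 and 65 without replicate 3. In simulated data of this comparison, 9% of genes changed 2-fold and 62% of genes changed 4-fold were recovered, so that most changes of 2-fold were not detectable at this spread.

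The endocardial population was compared with the mean of the 2 coronary populations on the log scale, so that a fold is against their geometric mean, to ask what distinguishes endocardium from coronary endothelium. Endocardial libraries had higher levels of the natriuretic peptide clearance receptor gene Npr3, the cadherin gene Cdh11 and the receptor gene Adgrg6, and of lymphatic and venous genes. Coronary libraries had higher levels of capillary genes such as Fabp4, Cd36 and Btnl9, of tip cell and VEGF response genes such as Apln and Kdr, and of nearly all mitosis genes tested. Npr3 (chromosome 15, 11839896 to 11907287, minus strand) had 2320 ± 203 CPM in endocardial, 25.7 in arterial and 49.0 in venous libraries, a log2 fold change of 6.03 ± 0.25 (adjusted p = 3.2e-08, edgeR). Fabp4 (chromosome 3, 10204088 to 10208576, minus strand), a fatty acid binding protein gene, had 120 ± 22.9 CPM in endocardial libraries against 1280 ± 143 and 1360 ± 71.9 (log2 -3.46 ± 0.17, adjusted p = 4.87e-10). Of 17103 genes, 1181 were higher and 1198 lower in endocardial libraries, and 2373 of these 2379 went in the same direction in each of the 3 batches, against 44.6% of all genes.

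**Figure D2:**
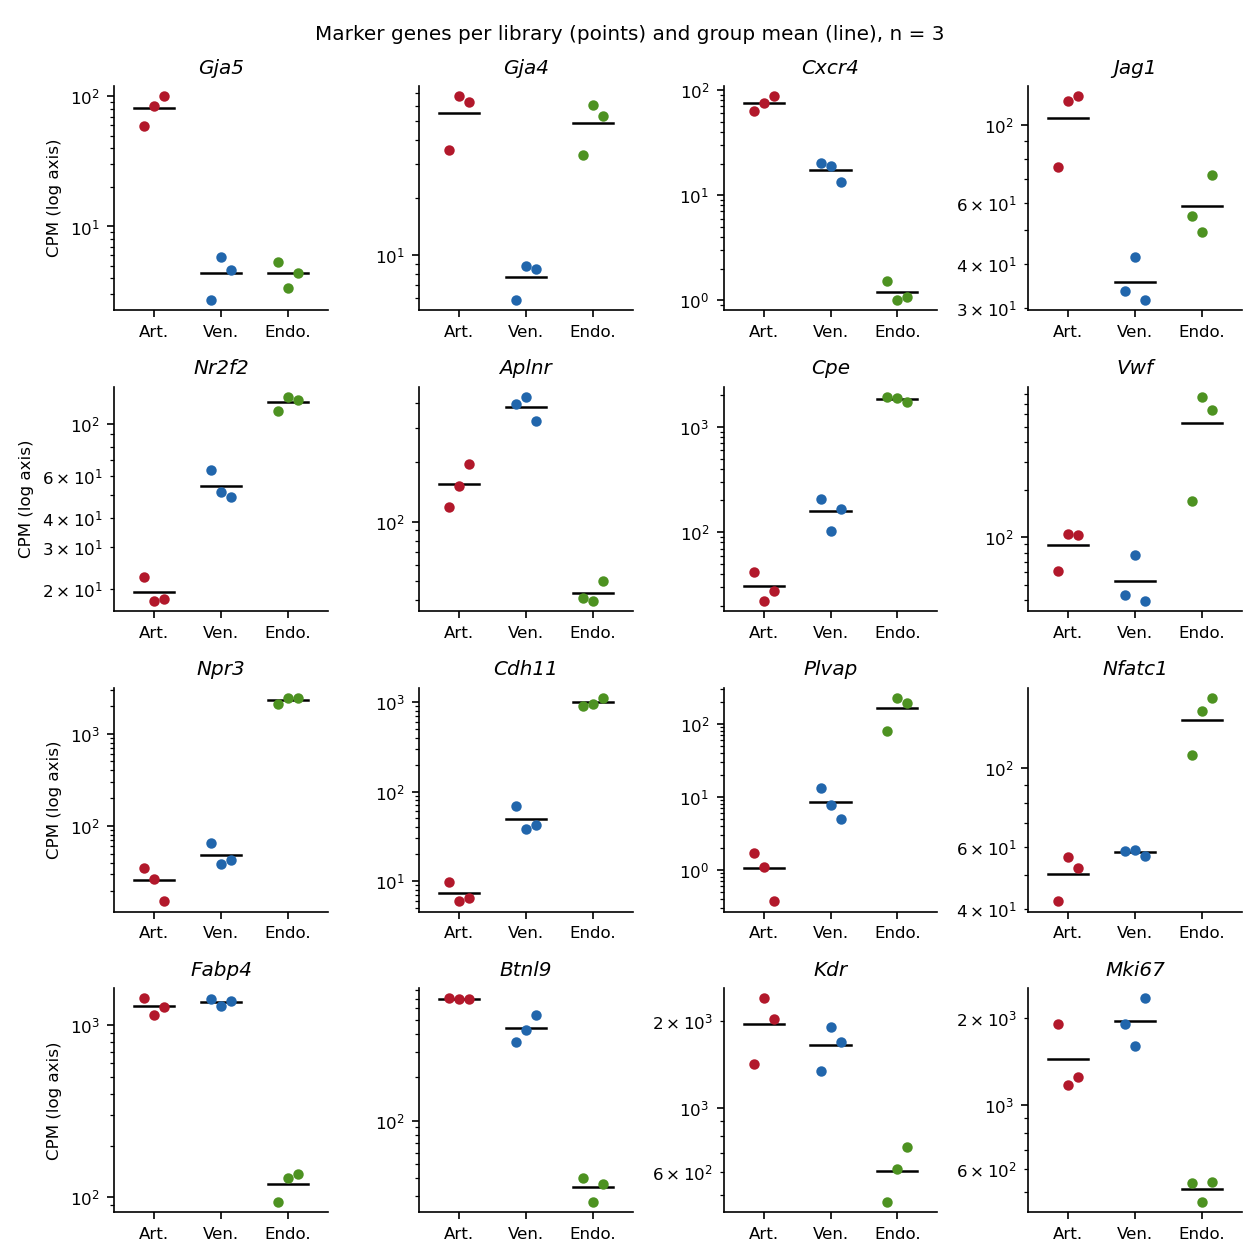
Levels of 16 marker genes in CPM on log axes, with 1 point per library and a line at the mean of 3 libraries for the arterial, venous and endocardial populations. Gja5 stands at 81.4 CPM in arterial against 4.40 and 4.38 CPM in venous and endocardial libraries, and Npr3 at 2320 CPM in endocardial libraries against 25.7 and 49.0 CPM.

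Of the 20 endocardial markers, 16 were higher in endocardial libraries, 1 was lower and 3 were not called (17 higher and 1 lower adjusted over the list alone), with a median of 3.75 and adjusted p = 3.16e-52 for the list. Adgrg6 (chromosome 10, 14402583 to 14545659, minus strand) had 431 ± 47.6 CPM against 3.25 ± 0.28 in arterial and 13.4 ± 0.68 in venous libraries (65.0-fold, adjusted p = 2.32e-13). Cdh11 (chromosome 8, 102632095 to 102785642, minus strand) had 997 ± 115 CPM against 7.33 ± 2.03 and 49.7 ± 16.9 (52.2-fold). Tmem108 rose by 5.31 ± 0.22, the forkhead factor gene Foxc1 by 3.54 ± 0.16, the diaphragm protein gene Plvap by 5.80 ± 0.49 and the transcription factor gene Nfatc1 by 1.35 ± 0.16 on the log2 scale. Bmp2, a BMP ligand gene, was the lower member (log2 -1.17 ± 0.33, adjusted p = 0.0227). That call ended without arterial replicate 1 (0.0534) or endocardial replicates 2 (0.0592) or 3 (0.0976). Outside the list, the largest rises by the same criteria included Smoc1, a calcium-binding matrix protein gene (139 ± 43.4 CPM against 0.738 ± 0.269 and 2.20 ± 0.223). They also included Mal (90.7 ± 24.4 CPM against 0.584 ± 0.220 and 2.16 ± 0.912) and the guidance ligand gene Slit3 (52.0 ± 25.7 CPM against 0.413 ± 0.360 and 1.95 ± 1.22). Cytl1 stood at 48.7 ± 18.3 CPM and Cldn11 at 70.3 ± 16.1 CPM, with log2 fold changes of 6.88 and 6.22 that became 8.64 and 6.96 without arterial replicate 2. The values for Cytl1 are fitted ones, since only that arterial library had counts for it.

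Lymphatic markers were higher in 7 of 10 cases, and 3 were not called (8 higher adjusted over the list alone), with a median of 4.66 and adjusted p = 6.51e-23. Prox1 had 241 ± 25.6 CPM in endocardial libraries against 7.30 and 18.3, and Reln, a secreted glycoprotein gene, rose by 4.48 ± 0.28 on the log2 scale. Among 15 venous markers 8 were higher, 2 were lower and 5 were not called (8 and 2 adjusted over the list alone; adjusted p = 7.09e-11). Their median was 1.91, or 1.84 with Lrg1, which had no count in the arterial libraries, at its bound. Cpe rose by 4.71 ± 0.23, Nr2f2 by 1.91 ± 0.16 and Vwf, encoding von Willebrand factor, by 2.93 ± 0.48, while Aplnr fell by 2.50 ± 0.19 and the semaphorin receptor gene Nrp2 fell by 1.25 ± 0.14. Fibroblast markers were higher in 9 of 15 cases, 1 was lower and 5 were not called (9 and 1 adjusted over the list alone; median 1.72, adjusted p = 3.05e-14), with Postn at 1050 CPM against 60.5 and 574 and Pdgfra at 112 CPM against 2.97 and 32.4. Against the venous libraries alone the list was not called. There 8 of the 15 members had a higher mean in venous libraries, among them Col1a1 (149 CPM against 26.7) and Col3a1 (526 CPM against 289).

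The arterial list was split, with 6 of 24 higher, 11 lower and 7 not called (6 and 13 adjusted over the list alone; median -0.78, adjusted p = 0.00401, and 0.0768 without endocardial replicate 1). Cxcr4 (chromosome 1, 128588199 to 128592293, minus strand) had 1.21 ± 0.28 CPM in endocardial libraries against 75.0 CPM in arterial libraries, and was 29.9-fold lower than in the coronary ones (adjusted p = 6.38e-09). Log2 fold changes were -2.11 ± 0.30 for Gja5, -1.57 ± 0.27 for Dll4, -1.60 ± 0.21 for Hey1 and -2.17 ± 0.19 for the binding protein gene Igfbp3. Gja4 rose by 1.25 ± 0.24, the matrix Gla protein gene Mgp by 3.46 ± 0.25 and the kinase gene Bmx by 2.79 ± 0.22. Sox17 stood at 3.43 ± 2.37 CPM against 59.1 and 39.5, with a log2 fold change of -3.82 that became -4.44 without endocardial replicate 1. Efnb2 (log2 -0.32, adjusted p = 0.15), Jag1 (log2 -0.06, adjusted p = 0.918) and Ephb4 (log2 0.69, adjusted p = 0.434) were not called, and Ephb4 passed without endocardial replicate 1 (0.0451).

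Of the 18 capillary markers, 17 were lower in endocardial libraries, and the remaining member, Fabp5, was 2.30-fold higher (17 and 1 adjusted over the list alone; median -3.00, adjusted p = 5.92e-32). Btnl9 had 34.7 ± 6.72 CPM in endocardial against 699 ± 3.54 in arterial and 439 ± 97.2 in venous libraries, and the scavenger receptor gene Cd36 265 against 2300 and 2200. In the same order, the homeobox gene Meox2 had 12.5 ± 2.58 CPM against 177 ± 21.8 and 197 ± 32.5, and the carbonic anhydrase gene Car4 2.03 ± 0.63 against 17.9 ± 8.46 and 22.7 ± 12.9. Of 28 genes of fatty acid uptake and oxidation, 10 were lower, 1 was higher and 17 were not called (12 and 2 adjusted over the list alone; median -0.30, adjusted p = 8.46e-07). Its members Fabp4, Meox2, Cd36, Lpl, Gpihbp1, Tcf15 and Fabp5 stood in the capillary list too. Fabp5 was the higher member, and the other shared members were all among the lower ones. This list is thus not separate evidence from the capillary list. In the tip cell and VEGF response list, 11 of 16 were lower and 5 were not called (1 higher and 13 lower adjusted over the list alone; median -1.42, adjusted p = 1.31e-12). Their log2 fold changes were -2.89 ± 0.23 for the peptide ligand gene Apln, -2.91 ± 0.28 for the nidogen gene Nid2, -2.41 ± 0.29 for Kcne3 and -1.56 ± 0.19 for Kdr. Further genes with large falls were Nr5a2 (25.1-fold), Depp1 (24.6-fold), St8sia6 (21.4-fold) and Prnd (15.8-fold). Dach1 had 11.7 CPM against 295 and 177. Ly6c1 (16.6-fold lower) has a near-identical copy, Ly6c2, with which the counting could have shared reads. Sez6l2 (0.922 ± 1.08 CPM against 43.7 and 20.7) had a log2 fold change of -4.99, and -6.63 without endocardial replicate 3.

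Cell cycle genes were lower in endocardial libraries. Of 32 mitosis genes, 29 were lower and 3 were not called (31 lower adjusted over the list alone), with a median of -1.38 and adjusted p = 2.92e-24. Mki67 (chromosome 7, 135689784 to 135716361, minus strand) had 513 ± 44.7 CPM against 1440 ± 403 in arterial and 1940 ± 369 in venous libraries (log2 -1.71 ± 0.18, adjusted p = 3.25e-06). The log2 fold change was -1.68 ± 0.16 for the kinesin gene Kif11, -1.65 ± 0.19 for the centromere protein gene Cenpf and -1.33 ± 0.16 for the topoisomerase gene Top2a. Of 32 DNA replication genes, 15 were lower and 17 were not called (21 lower adjusted over the list alone; median -0.76, adjusted p = 2.34e-06), with the sliding clamp gene Pcna lower by a log2 fold change of -0.91 ± 0.16. Per library, the median of the mitosis list relative to the coronary mean was -1.31, -1.47 and -1.31 in endocardial replicates 1, 2 and 3, and between -0.38 and 0.24 in the coronary libraries. The cell cycle inhibitor list was not called, although its member Cdkn1c, encoding p57, rose by 2.96 ± 0.13 (adjusted p = 1.53e-10).

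**Figure D3:**
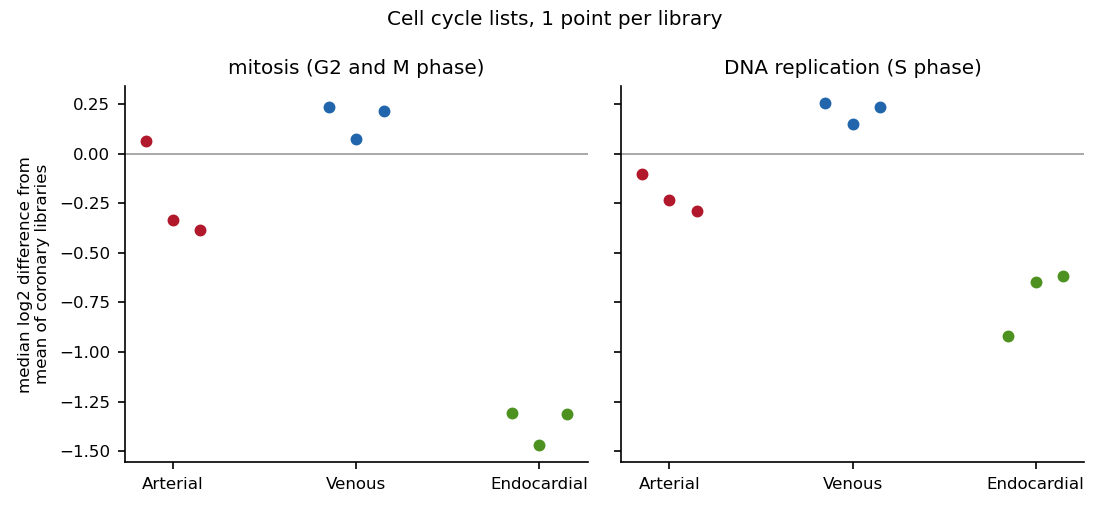
Median log2 difference of the mitosis and DNA replication lists from the mean of the coronary libraries, with 1 point per library for the arterial, venous and endocardial populations. The endocardial libraries sit between -1.47 and -1.31 for mitosis, below every coronary library.

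Among 30 BMP and TGF-beta genes 9 were higher, 3 were lower and 18 were not called (14 and 4 adjusted over the list alone; median 0.66, adjusted p = 1.49e-08). Tgfbi was higher by 4.44 ± 0.18, the receptor gene Bmpr1a by 3.76 ± 0.22 and the inhibitor of differentiation gene Id2 by 2.81 ± 0.22. Transition and valve genes partly restate other lists, with Cdh11, Nfatc1, Foxc1 and Bmp2 shared with the endocardial and Postn with the fibroblast list. In the transition and valve list, 8 of 23 were higher, 5 lower and 10 not called (8 and 5 adjusted over the list alone; median 0.50, adjusted p = 7.94e-07), and Vcan had 1000 CPM against 32.3 and 329. The matrix list (11 higher, 7 lower, 14 not called; 13 and 8 adjusted over the list alone) had a median of 0.35 and adjusted p = 0.0148, and adjusted p = 0.552 with an estimated correlation. It lost its call without arterial replicate 1 or endocardial replicate 3, at 0.0575 and 0.114. In it fibronectin (Fn1) rose by 2.49 ± 0.16 and Fbn2 by 2.72 ± 0.19, while Sparcl1 fell by 3.55 ± 0.18 and the collagen gene Col15a1 fell by 2.53 ± 0.21. The summed counts of the matrix members went the other way. They took 1.395%, 2.003% and 2.113% of counts in endocardial replicates 1, 2 and 3. Shares were 2.028%, 2.618% and 2.357% in the arterial and 1.78%, 2.43% and 2.446% in the venous replicates. The Wnt list (7 higher, 3 lower, 19 not called; 8 and 3 adjusted over the list alone) had adjusted p = 0.0371, and adjusted p = 0.146 with an estimated correlation, and lost its call without arterial replicate 1 (0.0582) or endocardial replicate 3 (0.114). Its members Apcdd1 and Wnt2 rose by 2.77 ± 0.31 and 4.70 ± 0.59. The summed counts of the Wnt members again went the other way. They took 0.1815%, 0.1768% and 0.1766% of counts in endocardial replicates 1, 2 and 3. Shares were 0.2201% to 0.2525% in the arterial and 0.1963% to 0.2281% in the venous libraries.

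Of 28 hypoxia and glycolysis genes, 11 were lower and 17 were not called (15 lower adjusted over the list alone; median -0.67, adjusted p = 3.48e-06, and adjusted p = 0.275 with an estimated correlation). Ankrd37 had a log2 fold change of -2.78 ± 0.27 and the oxygen sensor gene Egln1 one of -1.35 ± 0.17. The oxidative phosphorylation list (3 lower, 35 not called, 3 lower adjusted over the list alone) had adjusted p = 0.0371, and adjusted p = 0.498 with an estimated correlation, and lost its call without arterial replicate 1 or endocardial replicate 1, at 0.0624 and 0.167. The pan-endothelial list (2 higher, 7 lower, 7 not called; 3 and 8 adjusted over the list alone) had adjusted p = 0.0449, and adjusted p = 0.506 with an estimated correlation, and 0.289 without endocardial replicate 1. The angiopoietin receptor gene Tek rose by 1.05 ± 0.13, while the transcription factor genes Ets1 and Fli1 had log2 fold changes of -1.12 ± 0.13 and -1.07 ± 0.14. Mural markers (1 higher, 3 lower, 11 not called; 2 and 4 adjusted over the list alone) had adjusted p = 0.0170, and adjusted p = 0.150 with an estimated correlation, with Rgs5 lower by -3.46 ± 0.32 and Abcc9 by -2.72 ± 0.28. Immediate-early genes (5 higher, 19 not called, 7 higher adjusted over the list alone) had adjusted p = 0.0170, and adjusted p = 0.271 with an estimated correlation, and Fosb rose by 1.52 ± 0.14. Mitochondrially encoded genes (3 higher, 10 not called, 6 higher adjusted over the list alone) had adjusted p = 0.0497, and adjusted p = 0.382 with an estimated correlation, and lost the call without venous replicate 1 or any of the endocardial libraries, at 0.051 to 0.0895.

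The other 11 lists were not called between endocardial and coronary libraries, at adjusted p from 0.0722 to 0.998. They were the Notch, ephrin and guidance, shear stress, cell cycle inhibitor, chemokine, cardiomyocyte, epicardial, leukocyte, erythroid, neural and sex-linked lists. The cardiomyocyte list passed without arterial replicate 2, endocardial replicate 1 or venous replicates 2 or 3, at 0.0132 to 0.0399, and with fry (0.0393). Fry also called the chemokine (0.00194) and shear stress lists (0.0245), and lost the pan-endothelial (0.0527) and matrix lists (0.096). The count of 2379 genes was 1564 at 2-fold or more, and with 2 libraries per group it was 1265 without replicate 2 and 1290 without replicate 3. In simulated data of this comparison, 29% of genes changed 2-fold and 67% changed 4-fold were recovered, and 16 of the 113 genes called (14.2%) were unchanged, above the nominal 5%. The simulation changed 100 genes at each fold, against 2379 called here, so that these shares need not hold for the real data.

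**Figure D4:**
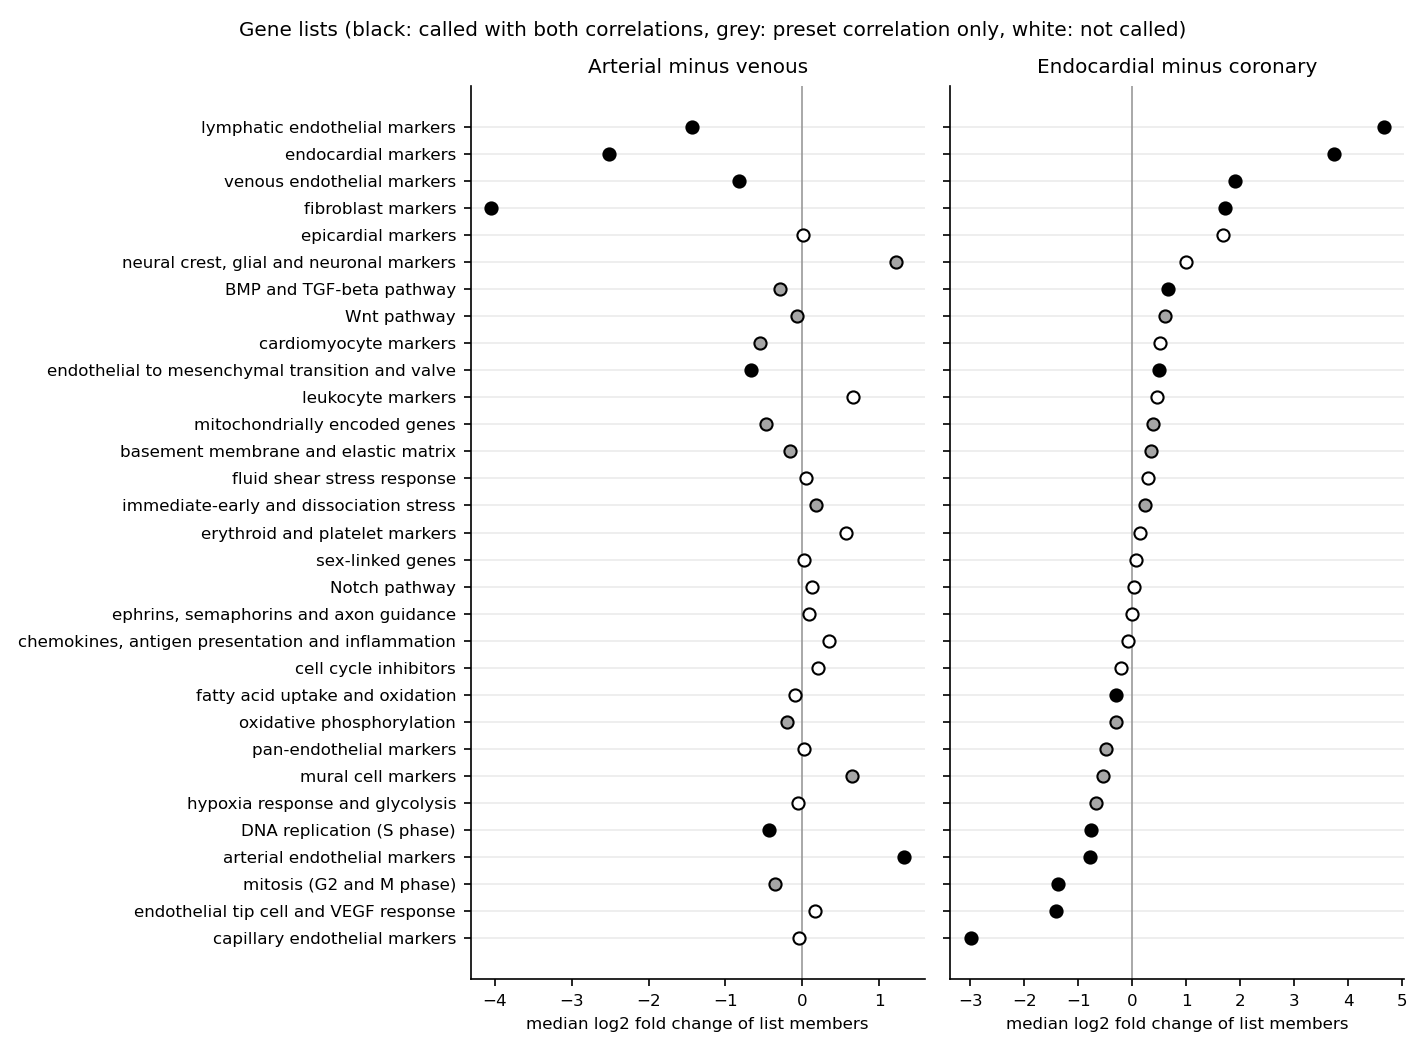
Median fitted log2 fold change of the members of each of the 31 gene lists for arterial minus venous (left) and endocardial minus coronary libraries (right). Points, 1 per list, are black where called with the preset and the estimated correlation, grey where called with the preset one only and white where not called; the capillary list stands at -3.00 on the right and is not called on the left, and the fibroblast list stands at -4.05 on the left and 1.72 on the right.

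Each coronary population was also compared with the endocardial one directly, to see which differences held for the arterial and which for the venous side. Arterial libraries were higher than endocardial ones in capillary, arterial, tip cell and mitosis genes and lower in endocardial, lymphatic, venous and fibroblast genes. Gja5 had 81.4 CPM in arterial against 4.38 CPM in endocardial libraries (log2 4.21 ± 0.34, adjusted p = 2.57e-07, edgeR), Cxcr4 rose 61.9-fold, St8sia6 43.4-fold, Depp1 31.8-fold and Nr5a2 31.0-fold. Among the falls, Smoc1 was lower by a log2 fold change of -7.52 ± 0.36, Plvap by -7.31 ± 0.72, Cdh11 by -7.09 ± 0.30 and Npr3 by -6.49 ± 0.35. Of 17103 genes, 1012 were higher and 984 lower in arterial libraries, 1992 of these 1996 in the same direction in each of the 3 batches, against 41.3% of all genes.

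Of 24 arterial markers, 15 were higher in arterial than in endocardial libraries, 5 lower and 4 not called (15 and 6 adjusted over the list alone; adjusted p = 8.05e-10). Dll4 (4.05-fold), Hey1 (5.29-fold) and Efnb2 (1.70-fold) were higher, Sox17 rose by 4.11 and by 4.73 without endocardial replicate 1, and Gja4 had 55.4 and 49.2 CPM and was not called (adjusted p = 0.86). Jag1 was 1.78-fold higher (adjusted p = 0.0217), a call that ended without arterial replicates 2 or 3 or endocardial replicate 2, at 0.103 to 0.126. Of 18 capillary markers, 17 were higher and 1 lower (17 and 1 adjusted over the list alone; adjusted p = 7.62e-33), with Fabp4 10.7-fold, Car4 8.78-fold and Kdr 3.21-fold higher. Tip cell genes (11 higher, 1 lower, 4 not called; 13 and 1 adjusted over the list alone; adjusted p = 3.94e-13) included Apln at 5.93-fold, and mitosis genes (28 higher, 4 not called, 30 higher adjusted over the list alone; adjusted p = 1.22e-17) included Mki67 at 2.81-fold. Of 20 endocardial markers, 17 were lower, 1 higher and 2 not called (18 and 1 adjusted over the list alone; adjusted p = 5.21e-55), with Nfatc1 lower by a log2 fold change of -1.46 ± 0.20. Of the venous list 8 of 15 were lower, 2 higher and 5 not called (9 and 2 adjusted over the list alone; adjusted p = 1.33e-12), with Nr2f2 at -2.66 ± 0.20 and Aplnr at 1.84 ± 0.20. Vwf was 5.88-fold lower (adjusted p = 0.0401) and kept its call without endocardial replicate 1 only, with 0.0777 to 0.164 without any of the other 8 libraries. Ephb4 was not called (adjusted p = 0.356), and was with the replicate block (0.0463) or without endocardial replicate 1 (0.029).

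Lymphatic markers were lower in arterial libraries (7 of 10, 3 not called, 7 adjusted over the list alone; adjusted p = 1.96e-19), as were fibroblast markers (10 of 15, 5 not called, 10 adjusted over the list alone; adjusted p = 8.94e-32). BMP and TGF-beta genes were lower (9 lower, 3 higher, 18 not called; 13 and 4 adjusted over the list alone; adjusted p = 2.34e-09). So were transition and valve genes (8 lower, 5 higher, 10 not called; 8 and 5 adjusted over the list alone; adjusted p = 5.59e-08). Fatty acid genes, several of which are capillary markers too, were higher (9 higher, 1 lower and 18 not called, or 9 and 1 adjusted over the list alone, camera adjusted p = 8.06e-06). The calls of 7 further lists were lost, with adjusted p = 0.0636 with an estimated correlation for Wnt (lower), 0.301 for hypoxia (higher), 0.0837 for DNA replication (higher), 0.261 for cardiomyocyte (lower), 0.0919 for mural (higher), 0.146 for mitochondrially encoded genes (lower) and 0.523 for the matrix list (lower). The matrix list also lost its call without arterial replicate 1 (0.0824). The summed counts of the Wnt and matrix members went the other way, with a larger share in the arterial library of each replicate number. The other 13 lists were not called, at adjusted p from 0.0511 to 0.899, and the replicate block called 2 of them, the pan-endothelial (0.0447) and the chemokine list (0.0498). The pan-endothelial list (0.0511) also passed without arterial replicates 1 or 3, endocardial replicates 2 or 3 or any of the venous libraries, at 0.0105 to 0.0494, and the immediate-early list without arterial replicate 1 (0.0304). Fry called the chemokine list (0.000247) and lost the matrix list (0.108). With 2 libraries per group the count of 1996 genes was 1003 without replicate 2 and 1065 without replicate 3. Cytl1, Cldn11 and Sez6l2, near 0 on 1 side, had log2 fold changes of -8.99, -8.28 and 5.53, which became -12.53 and -9.78 without arterial replicate 2 and 7.17 without endocardial replicate 3. The values for Cytl1 are fitted over arterial libraries with no count except in replicate 2.

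Venous libraries were higher than endocardial ones in capillary, tip cell and cell cycle genes and lower in endocardial and lymphatic genes. Aplnr rose 8.87-fold (log2 3.15 ± 0.21, adjusted p = 4.98e-08, edgeR), Meox2 15.7-fold, Dach1 15.1-fold and Nr5a2 20.3-fold, and Depp1 rose by 4.25 on the log2 scale. Npr3 was lower by a log2 fold change of -5.56 ± 0.34, Smoc1 by -5.98 ± 0.32, Mal by -5.39 ± 0.37 and the phosphodiesterase gene Enpp6 by -5.32 ± 0.40. Of 17103 genes, 994 were higher and 759 lower in venous libraries, 1749 of these 1753 in the same direction in each of the 3 batches, against 44% of all genes.

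Capillary markers were higher in venous than in endocardial libraries in 16 of 18 cases, 1 was lower and 1 was not called (17 and 1 adjusted over the list alone; adjusted p = 9.43e-37), with Fabp4 11.4-fold, Car4 11.2-fold and Kdr 2.72-fold higher. Mitosis genes (29 higher, 3 not called, 31 adjusted over the list alone; adjusted p = 1.01e-34) and DNA replication genes (16 higher, 16 not called, 22 adjusted over the list alone; adjusted p = 8.12e-11) were higher. Tip cell genes were higher too (10 higher, 6 not called, 12 adjusted over the list alone, camera adjusted p = 3.53e-13). So were fatty acid genes (10 higher, 1 lower and 17 not called, or 11 and 2 adjusted over the list alone, camera adjusted p = 6.33e-09), several of which are capillary markers as well. Mki67 was 3.78-fold and Apln 9.32-fold higher. Endocardial markers (11 lower, 9 not called; 2 higher and 13 lower adjusted over the list alone; adjusted p = 5.18e-27) and lymphatic markers (7 lower, 3 not called, 8 adjusted over the list alone; adjusted p = 1.39e-16) were lower. Cdh11 stood at -4.33 ± 0.26, Plvap at -4.29 ± 0.60 and Nfatc1 at -1.25 ± 0.19 on the log2 scale. Gja4 was lower by a log2 fold change of -2.68 ± 0.31 and Nr2f2 by -1.17 ± 0.19, while Cxcr4 was 14.4-fold higher. Gja5, at 4.40 and 4.38 CPM (adjusted p = 0.995), Efnb2 (adjusted p = 0.718) and Ephb4 (adjusted p = 0.776) were not called. Sox17 rose by 3.53, and by 4.16 without endocardial replicate 1, and Sez6l2 by 4.45, and by 6.10 without endocardial replicate 3.

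Among the named genes on the venous side, calls that ended with a single library left out were those of Dll4, Hey1 and Vwf. Over all alternatives, with whole batches left out too, 7 of 27 called named genes lost the call under at least 1 setting. Dll4 was 2.16-fold higher (adjusted p = 0.0247; 0.0789 to 0.116 without endocardial replicates 1 or 2 or venous replicate 2) and Hey1 1.74-fold higher (adjusted p = 0.0307; 0.0518 to 0.249 without any of the endocardial libraries or venous replicate 2). Vwf was 9.92-fold lower (adjusted p = 0.018; 0.0517 to 0.12 without arterial replicate 2, endocardial replicates 2 or 3 or any of the venous libraries). Jag1 missed the threshold (adjusted p = 0.0536) and passed with the replicate block (0.0313) or without arterial replicate 1 (0.0293). A further 7 list calls were lost, with adjusted p = 0.587 with an estimated correlation for pan-endothelial (higher), 0.165 for transition and valve (lower), 0.0796 for venous and for BMP and TGF-beta (both lower), 0.275 for hypoxia (higher), 0.396 for oxidative phosphorylation (higher) and 0.165 for immediate-early genes (lower). The pan-endothelial list also lost its call without endocardial replicate 1 (0.268) or venous replicate 2 (0.0577). The other 17 lists were not called, at adjusted p from 0.0503 to 0.791, among them the fibroblast list with 4 members higher, 6 lower and 5 not called (5 and 6 adjusted over the list alone; adjusted p = 0.67). The mural list (0.0503) was called with the replicate block (0.0463), with the size factors of DESeq2 (0.0447) and without arterial replicate 2, endocardial replicate 3 or venous replicates 1 or 3, at 0.00523 to 0.0438. The matrix list passed without endocardial replicate 1 (0.00194). Fry called the mural and chemokine lists (both 0.0179) and lost the pan-endothelial list (0.0779). The count of 1753 genes was 1130 without venous replicate 3, and with 2 libraries per group it was 801 without replicate 2 and 747 without replicate 3. The median of all genes in this comparison was -0.10, and -0.13 with the size factors of DESeq2, and the fold changes printed are not corrected for it.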

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

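The alternatives changed the counts of genes and ended some calls of named genes, but no named gene that was called and no called list changed direction. Directions of the other called genes were not checked. The whole-batch results were chosen after seeing the data. Between arterial and venous libraries the count of 183 became 439 without a filter on low counts and 405 with the DESeq2 Wald test, whose calls held all 183, with 179 and 173 genes higher in arterial libraries. The cause was not tested. Leaving out libraries gave 65 (without replicate 3) to 225 genes (without endocardial replicate 1). The cause of counts that fell or rose with libraries left out was not tested. The same range was 1265 to 2493 for endocardial against coronary, 1003 to 2251 for arterial against endocardial and 747 to 1871 for venous against endocardial libraries. A minimum of 2-fold left 1564 of the 2379 endocardial to coronary genes, by construction. With an estimated correlation the lists called fell from 17 to 7 (arterial against venous), from 20 to 12 (endocardial against coronary), from 18 to 11 (arterial against endocardial) and from 14 to 7 (venous against endocardial). Whether correlated members caused these losses was not tested. Of the named genes that were called, 20 of 38 (arterial against venous), 72 of 92 (endocardial against coronary), 24 of 29 (arterial against endocardial) and 20 of 27 (venous against endocardial) kept the call under every alternative, as did 7 of 17, 11 of 20, 11 of 18 and 7 of 14 lists in the same order. Among the named genes, signs changed only for those that were not called, and the cause was not tested. Between arterial and venous libraries Car4 ranged from -0.791 to 0.192 and Ccl21a from -5.281 to 0 with libraries left out, the 0 without venous replicate 3. Ccl21a had no count in arterial libraries, and its values are fitted. For endocardial against coronary libraries Jag1 ranged from -0.236 to 0.16, Xist from -0.255 to 0.614 and Ddx3y from -0.208 to 0.445, with -0.012 for Ddx3y under the replicate block. Gja4 ranged from -0.041 to 0.41 for arterial against endocardial libraries. For venous against endocardial libraries Gja5 was 0.006, and -0.026 with DESeq2 size factors, -0.07 with the stricter filter, -0.049 with the replicate block, -0.026 with DESeq2 and -0.4 to 0.421 with libraries left out, Efnb2 ranged from -0.235 to 0.058 and Ephb4 from -0.848 to 0.107. The replicate block gave 225, 2722, 2312 and 2097 genes in the order above, ended the call of Cldn11 between arterial and venous libraries (0.0848), began those of Ephb4 in arterial (0.0463) and Jag1 in venous against endocardial libraries (0.0313) and of Sox18 in endocardial against coronary libraries (0.0198), and changed no other call of a gene named in the text. At this depth 17103 of 41214 features passed the filter, and changes of the others were not tested.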

Other observations

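All tests weighed in this part were chosen after the results were seen. Single members of the epicardial, Notch and immediate-early lists differed between endocardial and coronary libraries, while the first 2 of these lists were not called and the immediate-early list lost its call with an estimated correlation (adjusted p = 0.271). Wt1, a zinc finger transcription factor gene known from the epicardium, was lower in endocardial libraries, with 189 CPM in arterial and 147 in venous ones (8.30-fold, log2 -3.05 ± 0.18, adjusted p = 2.79e-09). Only 2 of the 8 epicardial markers tested were called, Wt1 among them. Notch genes moved both ways, with the ligand gene Dll1 higher by 2.76 ± 0.25 and the glycosyltransferase gene Mfng and the target gene Nrarp at log2 fold changes of -1.90 ± 0.25 and -1.93 ± 0.26. The immediate-early genes Egr1 (log2 0.85 ± 0.12), Jun (log2 0.99 ± 0.16) and Fos (log2 0.71 ± 0.12) were higher in endocardial libraries, a set that is also known to respond to cell dissociation.

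Xist and the Y-linked gene Ddx3y were both present in every library. In each population replicate 2 had the highest Xist, at 1828, 2800 and 1994 CPM in arterial, endocardial and venous libraries, and the lowest Ddx3y, at 59.9, 34.6 and 31.7 CPM.

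Several imprinted genes stood among the endocardial genes, so that the hypothesis that imprinted genes rise as a group was tested with 53 listed genes. The idea came from 7 of them, and the values of 27 others had also been seen before the list was written, so that the full list partly restates what prompted it. Of 43 tested, 13 were higher in endocardial libraries, 4 were lower (Mest, Gnas, Grb10 and Asb4) and 26 were not called, with a median of 0.53. Asb4 lost its call without endocardial replicate 3 (adjusted p = 0.0761). The 19 genes not seen before were not called higher (14 tested, 2 higher, 12 not called; camera in limma, p = 0.127, and p = 0.156 with an estimated correlation), while 3.66% of 10000 random lists matched on expression had a median as high. Without only the 7 genes behind the idea, p was 0.048, 0.0614 with an estimated correlation, and 0.04% of random lists were as high. These values point different ways, and the hypothesis is left open. H19 had 31500 CPM against 5510 and 6280, Igf2 14300 against 3920 and 4050, Plagl1 6340 against 1600 and 1560, and Cdkn1c 1360 against 213 and 143. Igf2r (3910 against 872 and 1350) overlaps the transcript Airn, and the strandedness of the libraries was not stated.

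Fibroblast genes were higher in venous than in arterial libraries, and 2 technical explanations were weighed. Endocardial cells in the venous sort would bring all their abundant transcripts, and 10 genes chosen for a large endocardial fold allow a share of 1.02% to 5.31% (median 2.68%), while the fibroblast genes imply a median of 125% with Ogn set above all others, and 40.9% (13.1% to 693%) over the 10 at 10 CPM or more in endocardium. That argues against cells like the endocardial sort as a whole, but not against a part of it poor in those genes, as the 15 members of the endocardial list at 10 CPM or more implied 1.02% to 165% (median 6.65%), with Tbx20 higher in venous (136 CPM) than in endocardial libraries (88.0 CPM). Fibroblasts in the venous sort could be the cause, although the sort took CD31-positive cells only and would leave out fibroblasts without CD31, and so could expression by the venous cells themselves. All 15 of 15 members were lower in arterial libraries adjusted over the list alone, but that restates the pattern and would hold in either case, so that both stay open.

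Mitosis genes were lower in endocardial libraries, and 2 technical explanations were weighed. The lowest median of 10000 random lists matched on mean expression was -0.541, and -0.494 with exon length matched too, against -1.38 for the mitosis list. Loss of counts by abundance and a bias by gene length would have given random lists as low, and neither did. Slower cycling and a smaller share of cycling cells were not tested against each other, and both stay open.

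Lymphatic genes were higher in endocardial libraries, and lymphatic endothelial cells in that sort could be the cause. The prediction set for that cause was that all 10 tested members would be higher, and 7 were. Members that coronary cells express too need not rise with such cells, so that this count does not decide. Prox1 (241 CPM), Lyve1 (240 CPM) and Reln (148 CPM) were abundant, while Pdpn stood at 2.86 CPM and Itga9 and Sox18 were not called, although Sox18 was called lower with the replicate block (adjusted p = 0.0198). Without arterial replicate 1 the log2 fold change of Lyve1 moved from 5.52 to 6.21. The test cannot tell, as no lymphatic profile was analysed here.

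Other splits of the libraries were tried to see how the real split ranked among them. For arterial against venous, arterial against endocardial and venous against endocardial libraries, the real split was the 1 of 10 with the most genes (183, 1996 and 1753) and no other split called a gene in edgeR, but 10 splits are too few for a share under 0.05. For endocardial against coronary, the real split (2146 genes with the coronary libraries as a single group) was 1 of 84, and the highest other split called 109. These splits exchanged libraries between batches and used no block. With the replicate block and only the 27 splits that take 1 library from each batch, the real split called 2240 genes and the highest other split 25. Only 1 of 27 called as many, the smallest share that 27 splits allow, so that a first rank by chance alone is not likely. The other splits put endocardial and coronary libraries in the same group, which raises the spread within groups. Their counts thus do not show how many genes chance would call.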
